A study of Mus musculus with 2 samples.

How the data were processed

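Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in facial prominence tissue of mouse embryos at 14.5 days. The labels describe 1 group of 2 biological replicates of mixed sex. Replicate 1 was a pool of 24 embryos and replicate 2 a pool of 34. Nothing in the labels gives another tissue, stage or treatment, so no contrast between conditions could be made, and each test below is over genes or regions of these 2 libraries.

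The authors deposited peak lists, per the file headers in narrowPeak format on mouse build mm10. There were 3 lists per replicate and 6 lists over both replicates. The aligner, the peak caller and their thresholds are not given in the sources used here. The deposited signal value of a peak is the authors' strength of its summit, and it was used only to rank or describe peaks within a list. The deposited −log10 p of a summit was used in an alternative to the signal and to describe weak summits. The lowest deposited score in either replicate's IDR-thresholded list was 540. IDR stands for irreproducible discovery rate. The longer pseudoreplicated list of each replicate is called the relaxed list here. No read counts or depths come with the lists, so sequencing depth is unknown, and a region missing from a list is not shown to be closed.

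A deposited peak can hold several summits as separate rows, so rows that overlapped within a list were merged into regions, each with the signal of its strongest summit. A region was shared when regions of both replicates overlapped by at least 1 bp. Shared regions of the thresholded lists, taken with replicate 1 coordinates, were the main set. Chance overlap came from 100 circular shifts within chromosomes. Genes were the 21827 protein-coding genes of GENCODE M21, which is on the same assembly as mm10, with 41406 transcription start sites (TSSs). A promoter was the TSS ± 1 kb, and a gene counted as having an accessible promoter when a region of each replicate overlapped the window of the same TSS. Other regions were called distal and assigned to the nearest protein-coding TSS within 500 kb, whether or not they act on that gene. Coordinates are 1-based on mm10.

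Before the data were examined, 19 gene lists with 368 entries were fixed; 18 genes are on more than 1 list. Every entry matched the annotation. Promoter accessibility of each list was tested against all other genes with a two-sided Fisher's exact test. The median number of distal regions per gene was tested against 10000 random lists matched on domain length in 10 bins, with a two-sided permutation p. Regions found in 1 replicate and absent from the relaxed list of the other were compared per list with a two-sided Fisher's exact test. Each family was adjusted by the Benjamini-Hochberg method over the 19 lists, and 0.05 was the threshold. These tests take genes or regions as units, which are not independent replicates.

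The 20 consensus motifs, fixed beforehand, were matched on both strands within 50 bp of the strongest summit of each distal shared region. The same search was made in windows 500 bp away on both sides, and a motif was said to differ when the 95% Wilson intervals of the shares did not overlap. The reversed, uncomplemented consensus served as a control for single-base composition. It does not keep neighbouring bases: CAGCTG reversed holds a CG pair that the motif lacks, so it is not a full control. The intervals cover counting error only.

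Named genes were fixed by rule: the 20 genes with the most distal shared regions; for each list the 3 members with the most distal shared regions and the members without an accessible promoter, or the alphabetically first 2 where these exceed 3; and the genes nearest the 10 strongest distal shared regions. A further part of the rule, members of lists that differ between replicates, named none. Further members of the lists are named where stated below, and these were chosen after their values were seen.

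Alternatives were the relaxed lists, the upper part of each thresholded list by signal, the lists over both replicates, each replicate on its own, other overlap rules, promoter widths of 500 bp and 2500 bp, other ways of assigning distal regions, and other motif windows. The mean number of distal regions in place of the median was added after the data were seen.

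The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with bedtools 2.31.1 and BLAST 2.17.0 for checks. The functions were tested on simulated data. Random lists drawn from the 21827 genes gave an unadjusted p under the threshold for 2.63% of 380 lists in the promoter test and 0.263% in the distal test, so the distal test is conservative where most counts are 0. Planted lists were recovered in 20 of 20 simulations for each test. Those lists were extreme: nearly all members had open promoters, or all came from the genes with the most distal regions for their domain length. The random and planted lists were run on the regions of replicate 1, not on the main set. Recovery therefore does not show power for moderate differences. The overlap and merging functions gave the same numbers as bedtools on 3000 simulated regions, and 1000 of 1000 planted motifs were found. The lists of ranked peaks entered no comparison.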

Results

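Accessible chromatin was mapped in 2 pools of facial prominences from mouse embryos at 14.5 days, the tissue that forms the upper and lower face. The question the design allows is which promoters and distal elements were open in this tissue in both pools. Replicate 1 held 19880 accessible regions over 16.4 Mb and replicate 2 held 19698 over 16.3 Mb, or 19789 ± 129 regions (SD, n = 2). The median region was 815 bp wide in replicate 1 and 802 bp in replicate 2. About as many regions in each replicate, 72.0% and 70.1%, held several summits. The relaxed lists were longer, with 60203 and 61803 regions. Read depth is unknown for both libraries. No test across samples was possible with 2 replicates, so the tests below run over genes or regions and describe these libraries.

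The pools shared most of their accessible regions. Of the replicate 1 regions 73.3% (14563 of 19880) overlapped a region of replicate 2, and 73.7% of the replicate 2 regions (14515 of 19698) overlapped one of replicate 1. Circular shifts gave 1.28% on average and 1.52% at most for replicate 1. Promoters recurred more often than distal regions: 90.2% of the promoter regions of replicate 1 and 49.9% of its distal regions were in the thresholded list of replicate 2, and 93.4% and 48.3% in the other direction. Most distal regions without a partner were below the other replicate's threshold, since 87.7% of the distal regions of replicate 1 and 84.4% of those of replicate 2 were in the other's relaxed list. Recurrence rose with signal. In replicate 1 it was 41.3% in the weakest of 5 signal classes and 99.8% in the strongest, and in replicate 2 it was 54.1% and 98.1%. Across the 14563 shared regions Spearman's rho of the signals was 0.860 and Pearson's r of log2 signal 0.848; regions are not independent replicates.

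**Figure D1:**
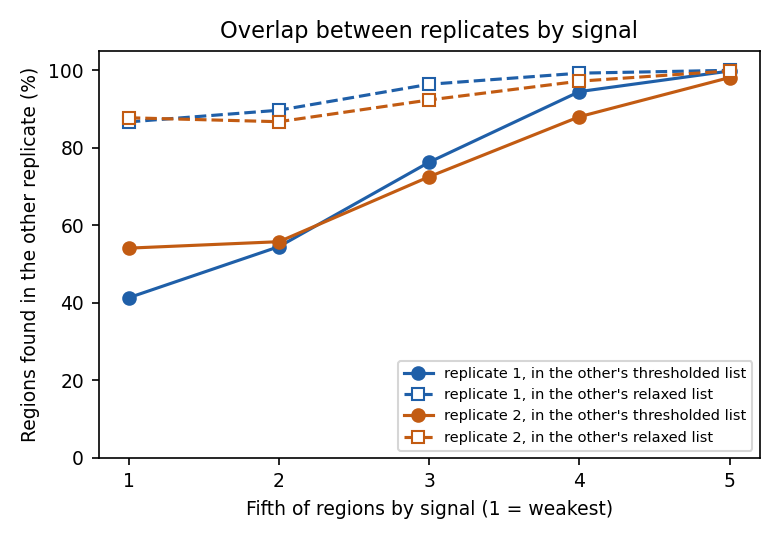
Share of each replicate's accessible regions found in the other replicate (y axis, percent) in 5 equal classes by signal (x axis, 1 is the weakest). Filled circles use the other replicate's thresholded list and rise from 41.3% to 99.8% in replicate 1 and from 54.1% to 98.1% in replicate 2; open squares use its relaxed list and lie between 86.6% and 99.9%.

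Most regions found in both pools lay at promoters. Of the 14563 shared regions, 71.3% (10388) overlapped a protein-coding promoter, against 3.01% of shifted regions (range 2.51% to 3.56% over 100 shifts), a 23.7-fold excess. Introns held 10.8% of the summits, intergenic sequence 16.6% and exons 1.26%. The promoter share depended on the list. It was 57.1% ± 1.16 (SD, n = 2) in the replicates' own thresholded lists, 36.9% of regions shared by the relaxed lists and 22.5% of the replicated list over both replicates. Promoter regions were stronger than distal regions in both libraries: the median signal was 12.7 against 8.77 in replicate 1 and 10.6 against 7.93 in replicate 2, a ratio of 1.39 ± 0.0795 (SD, n = 2). They were also wider, with medians of 962 bp and 701 bp.

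Promoters of 10970 of 21827 protein-coding genes (50.3%) were accessible in both pools, and 13607 (62.3%) in both relaxed lists. Housekeeping genes were the most often open. Of 16 members, 15 had an accessible promoter (93.8%; Fisher's exact adjusted p = 0.00328), the exception being Ubc, a polyubiquitin gene, whose promoter passed in the relaxed lists. Genes of other organs were the least often open. None of 39 Hox genes, which set position along the trunk and are silent in most facial neural crest, had an accessible promoter (Fisher's exact adjusted p = 2.73e-11), and neither did any of 15 liver genes such as Afp and Ahsg (adjusted p = 0.000267). Only Hcn4 of 12 heart genes (Fisher's exact adjusted p = 0.00886), Dazl of 14 germline genes (adjusted p = 0.00438) and Nkx6-1 of 12 pancreas genes (adjusted p = 0.00886) were open; these 3 names were chosen after the values were seen. Heart genes no longer differed in the relaxed lists (4 of 12; Fisher's exact adjusted p = 0.118), where Myh7 and Gata4 were open. Within 2500 bp of a TSS the germline list no longer passed (21.4%; Fisher's exact adjusted p = 0.0648). In the relaxed lists 4 Hox promoters passed, those of Hoxa1, Hoxa4, Hoxc13 and Hoxd1, and no liver promoter did. In the replicated list over both replicates 16 of 39 Hox promoters were open (41.0% against 66.5%; Fisher's exact adjusted p = 0.00422). Liver promoters were open there in 3 of 15 cases (Fisher's exact adjusted p = 0.00191), so both lists stayed below other genes. Heart genes did not pass there (6 of 12; Fisher's exact adjusted p = 0.342).

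Transcription factors of the facial mesenchyme, the connective tissue derived largely from neural crest, were open in part at the main threshold and in most cases in the relaxed lists. At the main threshold 20 of 46 promoters were accessible (43.5%, against 50.3% of other genes; Fisher's exact adjusted p = 0.424). In the relaxed lists 40 of 46 were (87.0%, against 62.3% of other genes; Fisher's exact adjusted p = 0.00166). The list also lay above other genes, without passing, in replicate 1 alone (56.5% against 54.2%, but 45.7% against 53.0% in replicate 2 alone) and in the IDR-thresholded list over both replicates (65.2% against 59.0%). In the conservative list over both replicates it was about level (56.5% against 55.4%). It passed in the replicated list (95.7% against 66.4%, Fisher's exact adjusted p = 4.92e-05). Members open at the main threshold included Msx1, Six1 and Six2, regulators of craniofacial growth. Six2 on chromosome 17 (85684277 to 85688274) had 3 distal shared regions, Six1 on chromosome 12 (73040015 to 73053887) had 2, and Msx1 on chromosome 5 (37820485 to 37824583) had 2. Nr2f1 and Tcf4, noted after their values were seen, also had 2 each. Alx3 and Alx4, aristaless-like factors of the frontonasal region, were not open at the main threshold and were in the relaxed lists. After their values were seen, 6 members are also named that were open in neither: Tfap2b, Dlx4, Hand1, Lhx8, Tbx22 and Shox2.

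Palate and cleft genes were open at about the level of other genes (16 of 30, 53.3%; Fisher's exact adjusted p = 0.903). In the relaxed lists 24 of 30 were open (Fisher's exact adjusted p = 0.110), and in the replicated list over both replicates 28 of 30 (93.3%; Fisher's exact adjusted p = 0.00227). Tooth genes lay below other genes without passing (6 of 17, 35.3% against 50.3%, Fisher's exact adjusted p = 0.298). In these lists Chd7, a chromatin remodeller, had 5 distal shared regions, and Spry2 and Tgfbr2, feedback and receptor genes of growth factor signalling, had 4 each. Bmp4 and Fgf8, secreted signals, had 1 distal region each. The promoter of Bmp4 opened only in the relaxed lists, and those of the enamel genes Ambn and Amelx in neither. Chd7 had thresholded regions at its TSSs in both replicates, with signals of 6.51 and 4.96, but not at the same TSS, and so counted as open only in the relaxed lists. Signalling targets, genes induced by Hedgehog, Wnt, BMP or FGF signals, were open in 14 of 19 cases (73.7%; Fisher's exact adjusted p = 0.101) and in 18 of 19 in the relaxed lists (94.7%; adjusted p = 0.00765). The promoters of Gli1 and Hhip, Hedgehog targets, were among the 4 that opened in the relaxed lists.

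Skeletal lists lay below other genes at the main threshold without passing. Chondrocyte genes were open in 7 of 21 cases (33.3% against 50.3%; Fisher's exact adjusted p = 0.193) and osteoblast genes in 5 of 18 (27.8% against 50.3%; adjusted p = 0.101). Chondrocyte genes were level in the relaxed lists (61.9% against 62.3%) and above other genes in the replicated list over both replicates (85.7% against 66.5%). Osteoblast genes stayed below in both (9 of 18 and 10 of 18). Neither list passed in either. Col1a1, the main bone collagen chain, had an open promoter and 3 distal shared regions on chromosome 11, and Pth1r and Sparc had open promoters and 2 distal regions each. The Col1a1 promoter was among the weakest open ones. Its signals of 4.44 and 3.57 lay at percentiles 0.50 and 0.16 of promoter signal in replicates 1 and 2. Among cartilage genes Wwp2 and Sox6 had 2 distal regions each and Col9a2 had 1; only Wwp2 of these had an open promoter. Promoters of Acan and Bglap, markers of mature cartilage and bone, were open in neither list type, and those of Cnmd and Alpl only in the relaxed lists.

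At the main threshold, markers of other cell types in the face were mostly not open, except that neuron genes were at the level of other genes. Skeletal muscle promoters were accessible in 4 of 21 cases (Fisher's exact adjusted p = 0.00984), endothelial in 2 of 14 (14.3%; adjusted p = 0.0150) and blood or immune in 2 of 16 (12.5%; adjusted p = 0.00849). The muscle result rested on replicate 2: in replicate 1 alone 8 of 21 were open (Fisher's exact adjusted p = 0.255), and in the relaxed lists 10 of 21 (adjusted p = 0.285). The endothelial difference was absent from the replicated list over both replicates (9 of 14, 64.3%; Fisher's exact adjusted p = 1). Distal regions were present at some genes with no open promoter, such as Ptprc, the pan-leukocyte gene, with 3, Cdh5, an endothelial cadherin, with 2, and Myod1, the muscle determination factor, with 1. The stretches nearest to their TSSs spanned 549 kb for Ptprc, 534 kb for Cdh5 and 50.6 kb for Myod1. Long stretches hold more regions by chance, and the germline gene Tnp1 likewise had 3 in 527 kb. The counts at Ptprc and Cdh5 therefore do not show elements of these genes. The stretch at Myod1 was short, so that reason does not apply to it, but nearness alone does not show that a region acts on a gene. The promoters of Acta1, Chrna1, Cldn5, Alas2 and C1qa were open in neither list type. Epithelial genes were open in 6 of 22 cases (27.3%; Fisher's exact adjusted p = 0.0641), a deficit that passed in the upper part of the lists by signal (18.2%; adjusted p = 0.0234) and in the conservative list over both replicates (27.3%; adjusted p = 0.0199). In the relaxed lists the direction turned without passing, with 15 of 22 open (68.2% against 62.3%), and so it did in the replicated list over both replicates (86.4% against 66.5%). The deficit was absent from the IDR-thresholded list over both replicates (59.1% against 59.0%). Epithelial genes had 2 distal shared regions at Grhl2, an epithelial transcription factor, and 1 each at Krt8 and Esrp2. Glia and melanocyte genes were open in 3 of 10 (Fisher's exact adjusted p = 0.298), neuron genes in 7 of 14 (adjusted p = 1) and forebrain and eye genes in 4 of 12 (adjusted p = 0.314). In the relaxed lists these rose to 5 of 10, 11 of 14 and 8 of 12. In the replicated list over both replicates they were 7 of 10, 13 of 14 and 9 of 12, and none passed in either. The neuron list differed between the pools, with 12 of 14 promoters open in replicate 1 and 7 of 14 in replicate 2, a difference that was not tested.

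**Figure D2:**
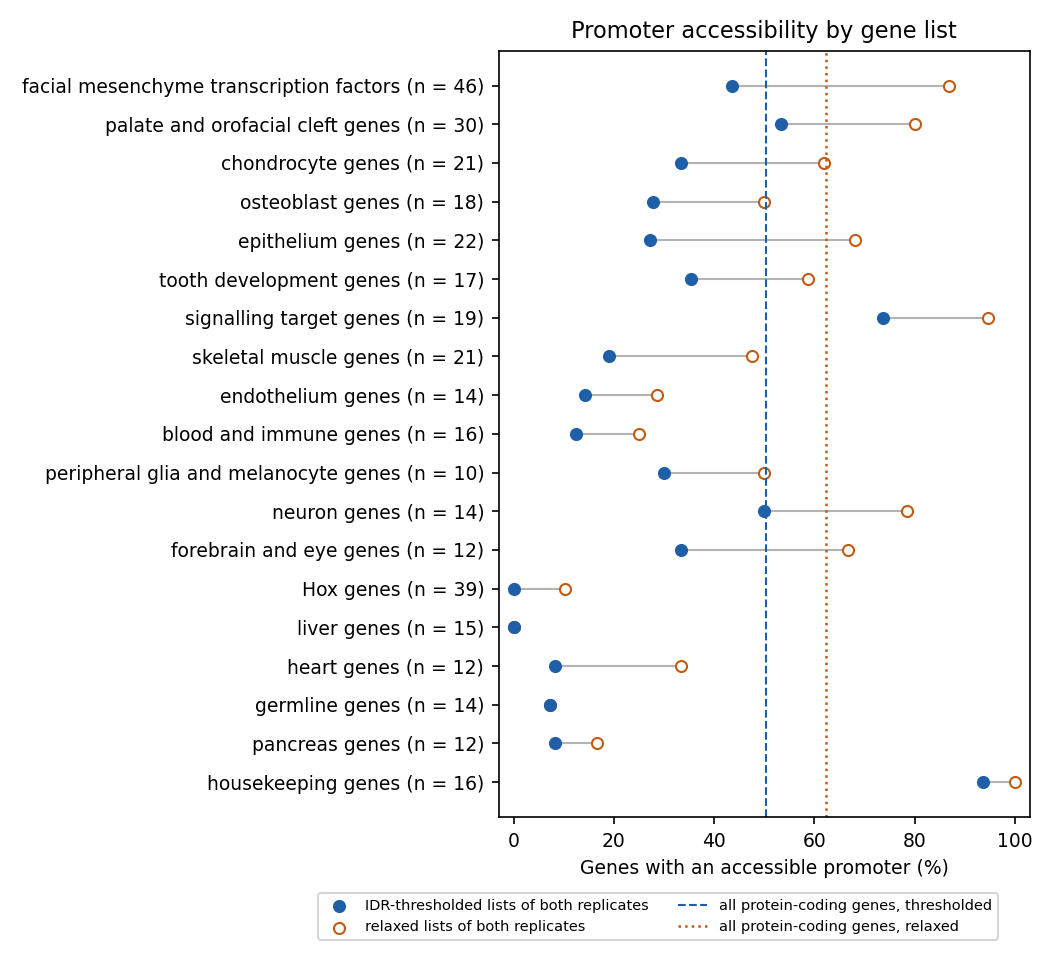
Share of genes in each of 19 lists whose promoter was accessible in both replicates (x axis, percent), for the thresholded lists (filled circles) and the relaxed lists (open circles); vertical lines mark all protein-coding genes, 50.3% and 62.3%. Facial mesenchyme transcription factors lie at 43.5% and 87.0%, Hox genes at 0% and 10.3%, and housekeeping genes at 93.8% and 100%.

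Signalling targets also had the most distal regions of any list. Their median was 1 distal shared region per gene against 0 in matched random lists (permutation p = 0.0070, adjusted p = 0.133 over 19 lists), and 15 of 19 members had at least 1. No list passed at the main threshold by the median, with 1 list at an unadjusted p under 0.05. The signalling list also missed the threshold in the upper part of the lists by signal and in the IDR-thresholded list over both replicates. It did pass in each replicate alone (median 3 in replicate 1, permutation adjusted p = 0.0038; median 2 in replicate 2, adjusted p = 0.0095) and in the relaxed lists (median 5 against 1, adjusted p = 0.0190). By the mean, a summary added after the data were seen, it had 1.47 regions per gene against 0.342 (adjusted p = 0.0038, the smallest the permutations allow), and palate and cleft genes had 0.867 against 0.347 (adjusted p = 0.0418). The palate result by the mean did not pass in replicate 1 alone (permutation adjusted p = 0.0735) or replicate 2 alone (adjusted p = 0.0699). Spry2 had 4 distal regions, Id3 and Spry4 had 3 each, and Gli1 had 1. Epithelial genes passed in replicate 2 alone (median 1 against 0, permutation adjusted p = 0.0076). Facial mesenchyme factors did not pass at the main threshold. By the median they passed in the replicated list (8 against 3, permutation adjusted p = 0.0057). In the relaxed lists their median missed (3 against 1, permutation adjusted p = 0.0532). By the mean they passed in the relaxed lists (3.67 against 2.35, permutation adjusted p = 0.0380), as housekeeping genes did. They also passed by the mean in replicate 2 alone (permutation adjusted p = 0.0266), not in replicate 1 alone (adjusted p = 0.458). Hox and pancreas genes had no distal shared region; random lists gave means of 0.0637 and 0.228.

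Genes with the most distal regions differed in how many more they had in the relaxed lists. Sox4 on chromosome 13 (8 regions), Gas1, Sorl1 and Tns3 (7 each) and Nfib, Hes1, Zfp516, Rgs3, Ncor2, Fam92b and Gm26897 (6 each) had many more in the relaxed lists, for example a total of 20 at Sox4, 24 at Gas1, 24 at Nfib and 18 at Hes1. Sox4 and Nfib encode transcription factors of progenitor cells, Gas1 a Hedgehog co-receptor and Hes1 a Notch target. Irf2bp2, Sertad2 and Chd2 had 6 each, and 11, 10 and 8 in the relaxed lists. Others gained few further regions in the relaxed lists: Eapp on chromosome 12 (8, and 9 in the relaxed lists), Tex14 on chromosome 11 (7 and 7), Zcchc13 on X (7 and 7), Klrb1c (6 and 7) and BC107364 (6 and 6), while Fcgr3 had 6 and 11. The 8 regions assigned to Eapp lay between 54710011 and 54739157, each within 1 kb of an annotated small nuclear RNA gene, as did the 7 assigned to Tex14; the 6 assigned to Fcgr3 lay within 1 kb of tRNA genes.

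The 10 strongest distal shared regions were narrow and intergenic. The strongest, on X from 143482937 to 143483180, 35.5 kb from a TSS of Pak3, had signals of 54.3 in replicate 1 and 52.0 in replicate 2, against a distal median of 8.77 and 7.93. The others lay nearest to Abcb11, G6pd2, Gm5426, Tyrp1, Galc, Myl12b, Frmd4a, Gm13283 and Hic2, with signals from 29.4 to 52.8 in replicate 1. The regions nearest to G6pd2, Tyrp1 and Galc were 1766 kb, 831 kb and 1198 kb from those genes. The regions nearest to Abcb11, G6pd2, Gm5426, Tyrp1 and Galc matched the mitochondrial genome at 94.9% identity or more.

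Distal summits carried motifs of architectural, bHLH and growth-related factors. CTCF sites were the most enriched: 3.52% of 4175 distal shared summits held the consensus against 0.108% of flanking windows, a 32.7-fold excess. Across the other settings the CTCF ratio ranged from 17.8 within 100 bp of the summit to 40.7 in replicate 1 alone. The E-box CAGCTG occurred at 16.8% of summits (95% Wilson interval 15.7 to 18.0) against 5.54% of flanks, the TEAD site GGAATGY at 5.44% against 2.68%, AP-1 TGASTCA at 2.59% against 1.59%, the NFI site TTGGCA at 6.85% against 5.14%, the ETS site at 0.766% against 0.120% and the POU octamer at 0.838% against 0.371%. In all 10 of 20 motifs were more frequent at summits and 3 were less frequent: the homeodomain site TAATTA (1.15% against 2.35%), the NR2F site AGGTCA (3.35% against 6.19%) and GATA AGATAAG (0.383% against 1.19%). Summit windows had 58.8% GC and flanks 48.1%. The reversed consensus was also enriched for TFAP2 (4.50-fold, against 2.27-fold for the motif itself) and for the E-box CACGTG (1.51-fold against 2.07-fold). The reversed CAGCTG and TEAD sequences had ratios of 1.33 and 0.959. Among the less frequent motifs the reversed homeodomain sequence had a lower ratio than the motif (0.238 against 0.490), the reversed GATA sequence had 0.487 against 0.323, and the reversed NR2F sequence had 0.996 against 0.542. RUNX, SOX, FOX, MEF2, HNF4 and the E-box CATATG did not differ from flanks, and no summit held the RFX palindrome. In replicate 2 alone RUNX (1.59) and SOX (1.45) were above flanks and CATATG (0.634) below. CATATG was also below flanks in windows within 100 bp of the summit (0.680). The E-box CAGATG, counted among the 10, lost its excess against windows 1000 bp away (1.15) and in the upper part of the lists by signal (1.15). The POU excess was not past its intervals in either replicate alone (ratios of 1.03 and 1.44), nor was the homeodomain deficit in replicate 2 alone (0.971). The ETS ratio fell to 3.11 in replicate 1 alone and 3.68 in replicate 2 alone, and the AP-1 excess was lost against windows 1000 bp away (1.30).

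**Figure D3:**
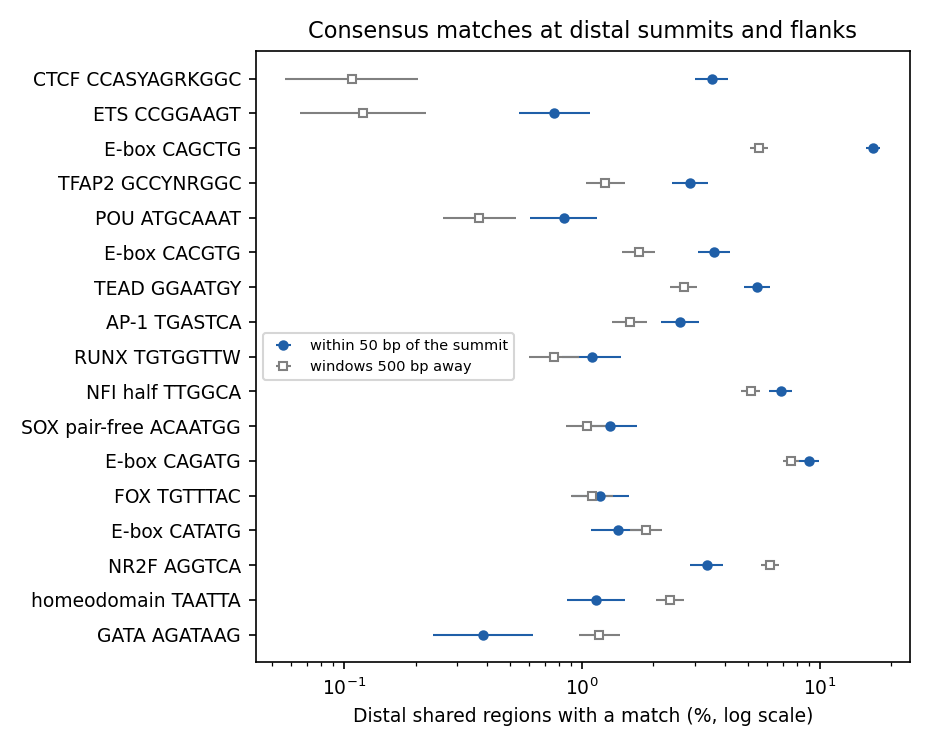
Share of distal shared regions with a consensus match (x axis, percent, log scale) within 50 bp of the summit (filled circles) and in windows 500 bp away (open squares), with 95% Wilson intervals, for the motifs found at 10 or more summits, ordered by ratio. CTCF lies at 3.52% against 0.108% and GATA at 0.383% against 1.19%.

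The X chromosome was sparse in accessible regions. It held 2.59 shared regions per Mb, below every autosome (4.00 on chromosome 14 to 9.31 on chromosome 11), and 45.2% of the density of the autosomes together. Of its protein-coding promoters 37.2% were accessible, against 51.3% on autosomes (range 41.0% to 62.5%). The embryos were of mixed sex. In the relaxed lists the X density was 31.9% of that of the autosomes.

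**Figure D4:**
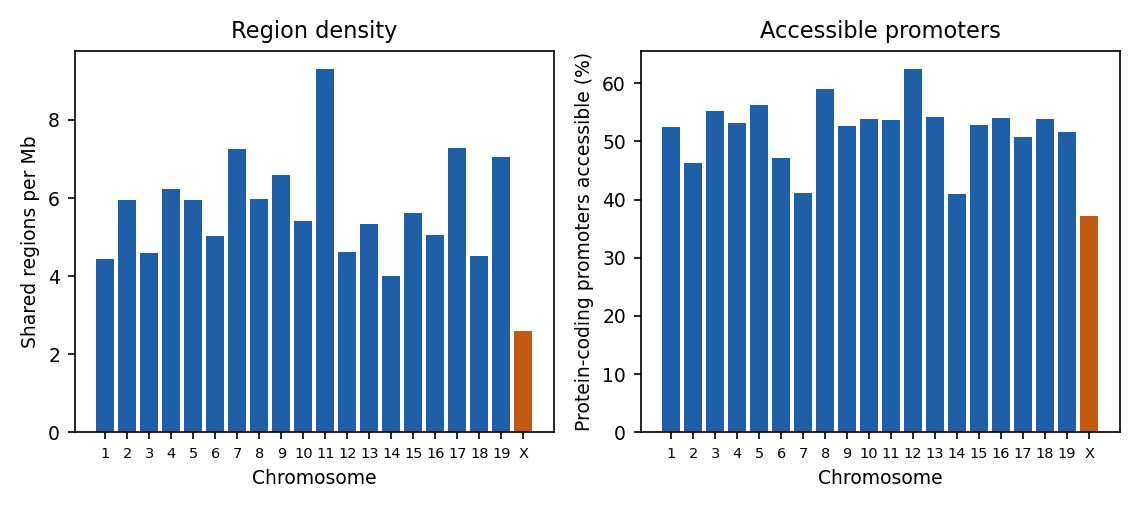
Shared accessible regions per Mb (left, y axis) and percent of protein-coding promoters accessible in both replicates (right, y axis) for each autosome and X (x axis). X has 2.59 regions per Mb and 37.2% of promoters, the lowest bar in both panels.

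Regions of 1 pool missing from the other's relaxed list had low signal. Among equal numbers of top-ranked regions there were 1068 in replicate 1 and 1431 in replicate 2. Their median signals were 6.96 and 6.95, against 9.59 and 8.58 in the full thresholded lists, and 6.09% and 5.87% lay at promoters. None of the 19 lists differed between them by Fisher's exact test, and 0 had an unadjusted p under 0.05. Against the other's thresholded list, 5201 and 5183 regions had no partner, and epithelial genes had 6 of these in replicate 1 and 23 in replicate 2 (Fisher's exact adjusted p = 0.0263, over regions that cluster by gene and are not independent).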

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

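Of the tests in this part, the one that matched promoters on signal was chosen after the result was seen.

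Peaks left out of the thresholded lists despite their score were flagged because no comparison used them. In replicate 1, 144 peaks of the ranked list reached the lowest score of the thresholded list and were absent from it, and in replicate 2 there were 147. Of these, 118 and 117 lay on the assembled chromosomes. Their median signal was below that of the peaks kept in both replicates (5.71 against 6.09 in replicate 1), and the highest were 47.7 and 44.9. With 2 samples in 1 group, no test for outlying samples or for differences between groups applied.

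The first pattern weighed was the change in the facial mesenchyme list, from 20 of 46 open promoters in the thresholded lists to 40 of 46 in the relaxed lists. A rise of this kind was not particular to this list. Epithelial genes went from 6 to 15 of 22, muscle genes from 4 to 10 of 21, and forebrain and eye genes from 4 to 8 of 12. Liver and germline genes did not rise. The authors' threshold acting on weak promoters stays open as an explanation. Of the 40 promoters open in the relaxed lists 50% passed the threshold, against 80.6% of all genes open there, and 48.7% (95% range 37.5 to 60.0) of random genes matched on relaxed promoter signal; the members' median signal percentile was 17.2. Matching on signal nearly fixes the share that passes, so this shows that the promoters were weak and does not decide the cause. Failure in a single pool stays open only for 7 of the 20 lost promoters, which were in the thresholded list of 1 replicate. The other 13 were in neither thresholded list, which argues against that explanation for them. Why these promoters were weak, for example openness in few cells, was not tested, since the design has 1 group and no biological explanation could be set against these.

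The second pattern was the very strong, narrow distal regions. Nuclear copies of mitochondrial DNA, which attract reads from the abundant organelle genome, are a candidate source for some of them: 5 of the 10 strongest matched the mitochondrial genome over at least 50 bp at 80% identity or more, and 0 of 200 sampled other distal regions did. Of all 4175 distal shared regions 13 matched, with a median signal of 23.3 in replicate 1 against 8.77 for the rest. Other nuclear copies stay open as a source, with a near-identical copy elsewhere for 2 of the 10, both of them among the mitochondrial matches. The regions nearest to Pak3, Myl12b, Frmd4a, Gm13283 and Hic2 had neither kind of match and are unexplained. No biological explanation was tested.

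The third pattern was a count of distal regions that rose little or not at all in the relaxed lists at 5 of the 20 genes named for the most distal regions, Eapp, Tex14, Zcchc13, Klrb1c and BC107364. Small RNA genes may explain most of their regions: 58.8% of the 34 (20) lay within 1 kb of a tRNA, snRNA, snoRNA or rRNA gene, against 3.76% of all distal shared regions. Reads shared between near-identical copies may add to this, since 50% (17 of 34) had another copy at 95% identity, against 2.00% of 200 sampled regions. The 7 regions at Tex14 had no such copy and the 8 at Eapp all had one. Long noncoding RNA promoters were too rare to account for them, at 14.7% of the regions. The regions at Zcchc13 and Klrb1c lay near none of these small RNA genes. The 20 regions near them lay at Eapp (8), Tex14 (7) and BC107364 (5), and regions at the same gene are not independent. Fcgr3, outside this set, had all 6 of its regions near tRNA genes and rose to 11 in the relaxed lists. Nearness to small RNA genes therefore does not by itself go with a count that stays flat.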

How the results depend on the processing

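The mean number of distal regions as a summary was chosen after the data were seen; the other settings were planned. The relaxed lists and the replicated list over both replicates, which hold weaker regions, moved many results; the replicated list also combines the replicates, so the threshold cannot be ranked alone. The cause of the changes below was not tested unless stated. With 1 replicate on its own the set is longer by construction.

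With the relaxed lists there were 60203 and 61803 regions, 65.1% and 63.3% of regions overlapped, rho was 0.737, the promoter share 36.9%, the signal ratio of promoters to distal regions 1.91, the X density 31.9% and the X promoter share 73.6% of the autosomes', 3 lists had more open promoters, 1 list had a higher median of distal regions, and the facial mesenchyme list turned to 87.0%. Rows in place of merged regions gave 45318 and 43966. Overlap was 73.7% and 74.7% in the upper part of the lists by signal, 73.6% of replicate 1 with equal numbers, 70.3% and 71.0% with 50% of both regions, and 64.7% and 66.8% of summits within 100 bp.

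The promoter share was 58.3%, 44.4% and 22.5% in the conservative, IDR-thresholded and replicated lists over both replicates, 56.3% to 57.9% with either replicate left out, and 70.0% and 73.2% with promoters of 500 bp and 2500 bp. Lists with more open promoters numbered 2, 2 and 4 in those 3 lists, and lists with fewer numbered 5 in the replicated list, where the facial mesenchyme list turned to 95.7% and the muscle list to 71.4%, and the muscle median of distal regions turned to 5. Lists with a higher distal median numbered 1 in the conservative list, 5 in the replicated list, 1 to 2 with either replicate left out, 1 within 50 kb of the TSS, 1 per 100 kb of domain, 2 by the mean and 5 by the mean in the relaxed lists.

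The signal ratio was 1.39 to 1.55 with either replicate left out. The X density was 40.3%, 34.5% and 26.8% of the autosomes' in the 3 lists over both replicates and 38.0% to 40.4% with a replicate left out; the X promoter share was 74.5% in the conservative and 73.6% in the replicated list, and 72.4% to 73.5% with a replicate left out. Judged against the other's thresholded list, 5201 and 5183 regions were in 1 replicate, and 1 list differed. The counts of motifs above or below flanks stayed within 1.5 times (8 to 11 and 3 to 4) in the 5 motif settings. A planned limit on the number of top regions for the comparison of regions found in 1 replicate could not be run, since both lists are shorter than it.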

Other observations

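The tests of long noncoding RNA TSSs, of spacing and of nearness to the facial mesenchyme list were set out before their results were seen. The comparisons of the other noncoding RNA classes and pseudogenes with shifted regions were not set out in this way. The comparison of epithelial and muscle genes was noted after the values were seen.

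Open chromatin outside protein-coding promoters included many noncoding RNA genes. Of the 403 annotated tRNA genes 34.0% (137) had a distal shared region within 1 kb, and 2.18% of distal shared regions lay that close to a tRNA gene, against 0.0326% of shifted regions. Small nuclear RNA genes had 1.22% of the regions within 1 kb (shifted 0.0982%), snoRNA genes 0.407% (shifted 0.131%) and miRNA genes 0.623% (shifted 0.111%). Pseudogenes had no excess, with 2.23% against 2.12%. Part of the distal set may be promoters of long noncoding RNAs: 11.3% of the 4175 regions (470) lay within 1 kb of such a TSS, against 1.30% on average and 1.72% at most in 100 shifts. Together 14.4% lay near a noncoding RNA gene other than a pseudogene.

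Regions assigned to epithelial genes were unevenly split between the pools when the thresholded lists were compared, but regions at the same gene are not independent and 2 libraries cannot give a difference between pools. Regions of replicate 2 without a partner in the thresholded list of replicate 1 included 23 assigned to 12 epithelial genes, with 6 at Grhl2, 4 at Pitx1 and 2 each at Esrp1, Krt18 and Perp, and replicate 1 had 6. Muscle genes did not pass, with 15 regions at 10 genes in replicate 1, 2 each at Myod1, Pax7, Msc, Tnnt3 and Ttn, and 4 in replicate 2 (Fisher's exact adjusted p = 0.182). In the planned comparison, against the other's relaxed list, neither list differed (Fisher's exact adjusted p = 0.570 for both).

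Facial mesenchyme factors of the TWIST and ALX families are known to bind jointly to a composite of an E-box and a homeodomain site, so 32 spacings and orientations of CAKMTG with TAAT were counted within 100 bp of the 24734 distal summits shared by the relaxed lists. One arrangement stood out: an E-box followed after 6 bp by ATTA occurred at 254 summits, 3.73 times the mean of the other arrangements. In the flanks the same arrangement had 1.19 times the mean, with 107 windows over both sides. The flanks had a high count of their own at another arrangement. There TAAT directly after the E-box occurred in 252 windows, against 69 summits, so a single spacing can also stand out away from summits. The next most frequent arrangement at summits, TAAT after 4 bp, had 122 summits. It overlaps the arrangement with ATTA after 6 bp where the homeodomain site is TAATTA. The fixed distance may reflect joint binding of such factors in this tissue, a hypothesis that no binding data here test. The homeodomain site alone was less frequent at thresholded distal summits than in flanks (ratio 0.490), but its reversed sequence was too (0.238), so that deficit is not specific to the site.

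These summits were not shown to lie near the facial mesenchyme factors themselves. Of the 254 regions 0.394% (1, at Hand2) were assigned to the fixed list, against 0.686% of the others, too few to tell (Fisher's exact p = 1).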
